A study of Rattus norvegicus with 9 samples.

How the data were processed

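Gene expression was measured by RNA sequencing in 9 libraries from cultured rat cortical neurons. The neurons came from embryonic day 18 animals and were infected with lentivirus after 14 to 15 days in culture, and RNA was taken 72 hours after infection, per the labels' protocols. The titles give 3 groups of 3 libraries: a control shRNA, Trank1 shRNA1 and Trank1 shRNA2. An shRNA (short hairpin RNA) is processed in the cell into a small RNA that lowers the transcript it matches. A treatment label of the shRNA2 libraries gives that hairpin another number than their titles do, and 1 protocol label speaks of an empty vector where the titles and the design text speak of a control shRNA. The titles were followed in both cases. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

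The authors deposited 1 table of FPKM values (fragments per kilobase of gene, scaled to the mapped fragments of the library) for 32883 genes, with 1 column per library. Trimmomatic 0.32, HISAT2 and featureCounts are named per the submitters' processing notes, and the other versions and the genome build are not given in the sources used here. FPKM corrects for gene length and for the library's total, so a strong rise of some abundant genes lowers the values of all others in that library. The summed FPKM ranged from 164501 to 172646 per library, and 9475 genes were listed at 0 in all 9. Read totals are not given in the table. Low FPKM values fall on steps of whole reads, and the offset of these steps between libraries gave the depth relative to control replicate 1. With these offsets 23.9% of 2026 low genes (FPKM below 0.3) had all values above 0.05 within 0.1 of a whole number of reads. In 20 shuffles of the offsets the share was at most 4.69%. The offsets were fitted on values of the same range, so this check is not independent of them. Relative depth ranged from 0.927 to 1.28, with a mean of 1.16 ± 0.145 (SD, n = 3) for control, 1.13 ± 0.0860 for shRNA1 and 0.981 ± 0.0768 for shRNA2.

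The table names genes by Ensembl identifiers only. The reference table used here (assembly GRCr8) pairs symbols with other identifiers, and 0 of the 32883 identifiers matched, so the files used here do not pair the identifiers with names. For that reason the level of Trank1 and the 23 gene lists fixed beforehand (neuronal, glial and stress genes among others, 14 to 39 genes each) were not analysed here, and the tests of those lists (camera and fry) were not run. The rule for named genes, fixed before the data were examined, asked for Trank1, for the genes with a symbol that had the largest rise or fall with each hairpin and between the hairpins, for up to 4 members of each list, and for genes called with both hairpins in the same direction, ranked by the smaller of their 2 fold changes. Only the last part could be applied without symbols. It asked for more genes in each direction, and only the first 2 that rose and the first 2 that fell are given, by identifier. Other genes are described without identifiers.

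Genes with a mean of at least 1 FPKM over the 9 libraries were tested, 11474 in all, which held 98.8% of the summed FPKM. Values were used as log2(FPKM + 1), and fold changes are on that scale, which understates the change of low genes. A model with a mean per group was fitted over all 9 libraries with limma 3.58.1 in R 4.3.3, with a moderated variance that followed the mean expression (eBayes with trend), and Benjamini-Hochberg adjustment was applied within each comparison. A gene was called at an adjusted p below 0.05. The comparisons were each hairpin against control, the mean of both hairpins against control, and shRNA2 against shRNA1, which is the test of a difference between the hairpins. Count-based tests were not run, since the values are FPKM. Both hairpins are compared with the same control libraries. Therefore 100 simulated experiments without effects, with the real residual spread, gave the agreement that independent noise of shared control libraries produces. Figures and the depth estimate were made in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

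The procedure was tested on simulated data with 200 changed genes among 11474. In the simulated comparison of shRNA1 with control, 46% of genes changed by 0.25 on the log2 scale were recovered, 92% at 0.5, 98% at 1 and 100% at 2. In that of shRNA2 with control the shares were 32%, 92%, 98% and 100%. False calls made up 8.20% and 4.73% of the calls. These simulations changed few genes and drew noise independently for each gene. Their shares need not hold for the real comparisons, where far more genes were called. Alternatives tried were other pseudocounts, filters, scalings, variance models and thresholds, library weights, fits of only the groups compared, the replicate number as a block, and leaving out each library in turn.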

Results

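Rat cortical neurons in culture were infected with lentivirus carrying a control shRNA or 1 of 2 hairpins against Trank1, and their RNA was sequenced 72 hours later, with 3 libraries per group. The design asks which transcripts change when Trank1 is lowered, and the use of 2 hairpins allows changes common to both to be told from changes seen with 1. The submitters state an infection efficiency above 80% and a mean reduction of Trank1 by 43.4% with shRNA1 and 35.7% with shRNA2. Since a label of the shRNA2 libraries gives another hairpin number, it is uncertain that the second value belongs to their hairpin. The Trank1 level itself was not analysed here, because the files used here do not pair gene identifiers with names, so the knockdown was not checked in these libraries. Between 18965 and 19678 genes were above 0 FPKM per library, and 11474 genes with a mean of at least 1 FPKM were tested. Sequencing depth, as estimated from the low values, ranged from 0.927 to 1.28 times that of control replicate 1.

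The libraries separated by hairpin. The first principal component held 79.1% of the variance and placed the shRNA2 libraries, with scores from 40.5 to 41.7, apart from the control and shRNA1 libraries, with scores from -22.2 to -17.0. The second component held 9.70% and separated the shRNA1 libraries (7.21 to 16.2) from the control libraries (-12.1 to -11.0). Control libraries correlated with shRNA1 libraries at r between 0.977 and 0.986 and with shRNA2 libraries at r between 0.899 and 0.905, while libraries of the same group correlated at r between 0.988 and 0.995 (Pearson, across genes, which are not independent replicates). Replicate 1 of both hairpin groups stood apart from replicates 2 and 3 on the third component (3.74% of variance), with scores of 8.75 for shRNA1 and 13.2 for shRNA2, against -6.57 to 0.23 for the other 7 libraries.

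**Figure D1:**
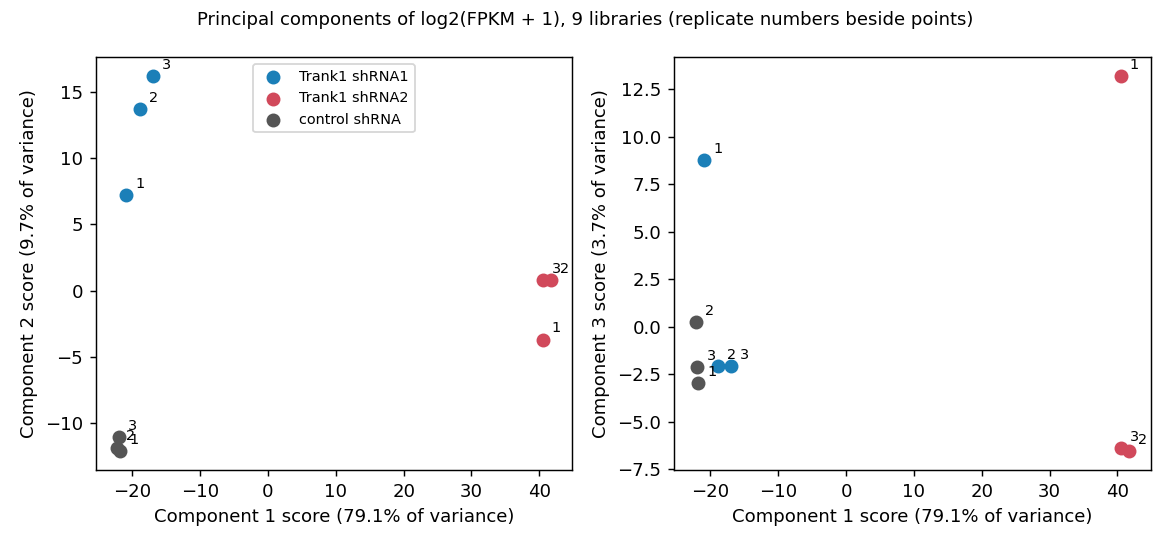
Scores of the 9 libraries on principal components 1 and 2 (left) and 1 and 3 (right) of log2(FPKM + 1), each point a library with its replicate number and each axis in score units. The shRNA2 libraries lie near 41 on component 1, and replicate 1 of both hairpin groups lies above the other libraries on component 3.

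With shRNA1, most of the called changes were small. Of 11474 genes, 3323 (29.0%) were called against control, 1279 higher and 2044 lower, with a median absolute log2 change of 0.27 among them. At a pseudocount of 1, 46 genes changed 2-fold or more, 15 of them higher and 31 lower, and the number was 102 and 117 with pseudocounts of 0.1 and 0.01 and 95 with TPM scaling. The 15 genes raised 2-fold or more took 1.05% ± 0.113 of the summed FPKM in shRNA1 libraries and 0.463% ± 0.0592 in control libraries (SD, n = 3), and the 31 lowered ones took 0.236% ± 0.0308 and 0.613% ± 0.00275. One of the most abundant transcripts of these neurons, chosen after its values were seen, was among those that rose: it ranked 19 in control libraries at 536 ± 77.3 FPKM and reached 1230.0 ± 144 with shRNA1 (log2 change 1.20, limma adjusted p = 0.000304, n = 3 per group). Without it the other 14 genes raised 2-fold or more took 0.305% ± 0.0241 with shRNA1 and 0.142% ± 0.0134 in control. The largest fall was from 47.6 ± 0.294 to 9.65 ± 0.968 FPKM (log2 change -2.19, adjusted p = 4.56e-07). The 3 libraries of each group did not overlap for 45.5% of the tested genes, where chance gives 10%. The share of called genes that were higher, 38.5%, depended on the scaling and was 53.05% with median-of-ratios factors and 52.4% after quantile normalization. The number called was 2167 without shRNA1 replicate 3 and 5235 with library weights.

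With shRNA2, more genes changed strongly, and a set of transcripts nearly silent in control neurons appeared. Among called genes the median absolute log2 change was 0.32, against 0.27 with shRNA1, so most called changes were small here too. In all, 5811 genes (50.6%) were called against control, 2962 higher and 2849 lower, and 654 changed 2-fold or more, 428 higher and 226 lower. The latter number was 883 and 914 with pseudocounts of 0.1 and 0.01 and 855 with TPM scaling. The balance of all calls turned to 2797 higher and 2990 lower with TPM scaling and to 2548 and 3652 after quantile normalization. The rises included 183 genes raised 4-fold or more and 30 raised 16-fold or more, against 38 and 2 that fell as far. A group of 26 genes rose from a mean below 1 FPKM in control to 10 FPKM or more. The largest rise took a transcript from 0.316 ± 0.0678 to 601 ± 37.3 FPKM (SD, n = 3; log2 change 8.84, limma adjusted p = 3.37e-11), and the next from 0.521 ± 0.0527 to 361 ± 32.1 FPKM (log2 change 7.89, adjusted p = 5.79e-12). Their log2 changes with shRNA1 were 0.46 and 0.24. The 183 genes raised 4-fold or more together took 0.788% ± 0.0496 of the summed FPKM in control, 1.32% ± 0.128 with shRNA1 and 8.01% ± 0.522 with shRNA2. Without the gene ranked 19 in control, which is among them, the other 182 took 0.466% ± 0.00613, 0.576% ± 0.0497 and 6.58% ± 0.336. The largest fall took a transcript from 187 ± 8.70 to 9.88 ± 1.33 FPKM (log2 change -4.12, adjusted p = 1.27e-09). The 38 genes lowered 4-fold or more went from 1.63% ± 0.0376 of the summed FPKM in control to 0.281% ± 0.0242, and took 1.26% ± 0.167 with shRNA1. Of the 20 most abundant transcripts in control, 16 were lower with shRNA2, 2 were higher and 2 were not called, and with shRNA1 the numbers were 4, 2 and 14. The groups did not overlap for 61.3% of tested genes, where chance gives 10%.

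**Figure D2:**
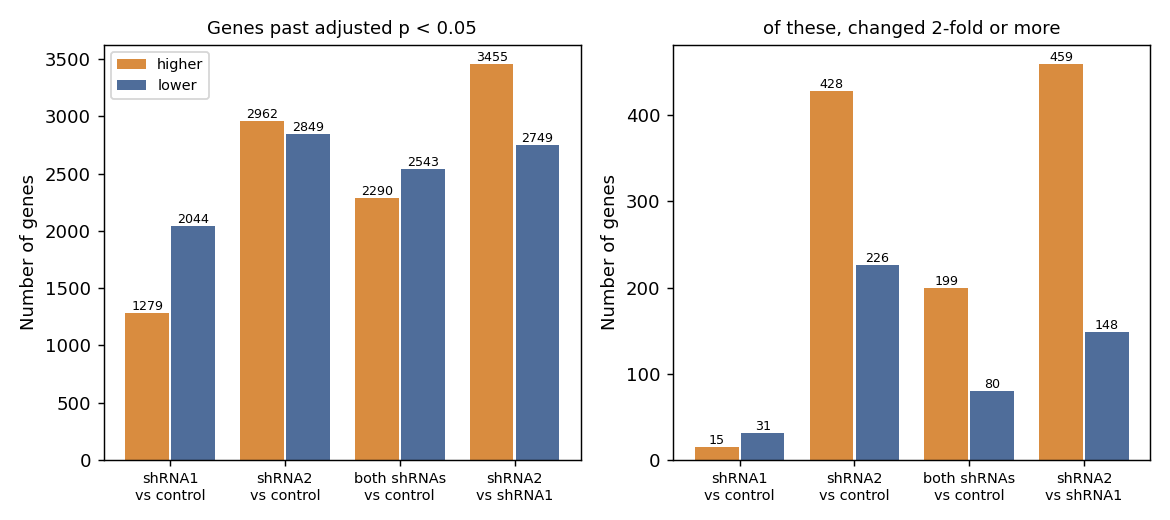
Number of genes past an adjusted p of 0.05 in each comparison (left) and the part of them changed 2-fold or more (right), with bars for genes higher and lower in the group named first. At a pseudocount of 1, 46 genes changed 2-fold or more with shRNA1 and 654 with shRNA2.

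Genes moved the same way by both hairpins numbered 1537, of which 591 were higher and 946 lower, and 510 genes moved in opposite directions. Independent lists of these sizes would share 330 higher and 508 lower genes and would oppose each other in 845. Only 16 genes changed 2-fold or more in the same direction with both, 11 higher and 5 lower. ENSRNOG00000002802 rose from 11.1 ± 1.21 FPKM in control to 32.1 ± 8.72 with shRNA1 and 224 ± 15.5 with shRNA2 (SD, n = 3), log2 changes of 1.42 ± 0.16 (SE, adjusted p = 0.000243) and 4.21 ± 0.16 (adjusted p = 1.69e-08). ENSRNOG00000006151 was at 0.040 ± 0.0364 FPKM in control, 2.01 ± 1.55 with shRNA1 and 2.62 ± 1.31 with shRNA2, log2 changes of 1.36 ± 0.43 (adjusted p = 0.0400) and 1.72 ± 0.43 (adjusted p = 0.00760). At these low levels the fold depends on the pseudocount, and the log2 changes were 3.42 and 4.15 with 0.1 and 4.94 and 5.78 with 0.01. Its call with shRNA1 ended when any of 6 of the 9 libraries was left out, with adjusted p from 0.00169 to 0.138 over the 9, and its shRNA1 values of 0.258, 2.55 and 3.23 FPKM spread widely. Replicate 1 was the lowest with shRNA2 too, at 1.11 FPKM against 3.455 and 3.28. ENSRNOG00000012410 fell from 32.0 ± 1.03 FPKM to 6.66 ± 1.87 with shRNA1 and 8.67 ± 2.02 with shRNA2, log2 changes of -2.13 ± 0.17 (adjusted p = 4.83e-05) and -1.79 ± 0.17 (adjusted p = 1.95e-05). ENSRNOG00000000805 fell from 120 ± 3.25 FPKM to 46.0 ± 3.42 and 30.0 ± 1.97, log2 changes of -1.36 ± 0.064 (adjusted p = 2.38e-06) and -1.96 ± 0.064 (adjusted p = 6.48e-09). For each of these 8 comparisons with control the values did not overlap, and an exact two-sided permutation test of 3 against 3 gave p = 0.1, the smallest it can give. The abundant transcript ranked 19 in control was raised further by shRNA2, to 2419 ± 363 FPKM (log2 change 2.17, adjusted p = 8.69e-07), and ranked 2 there. The number moved the same way was 1020 without control replicate 2 and 2591 with library weights.

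**Figure D3:**
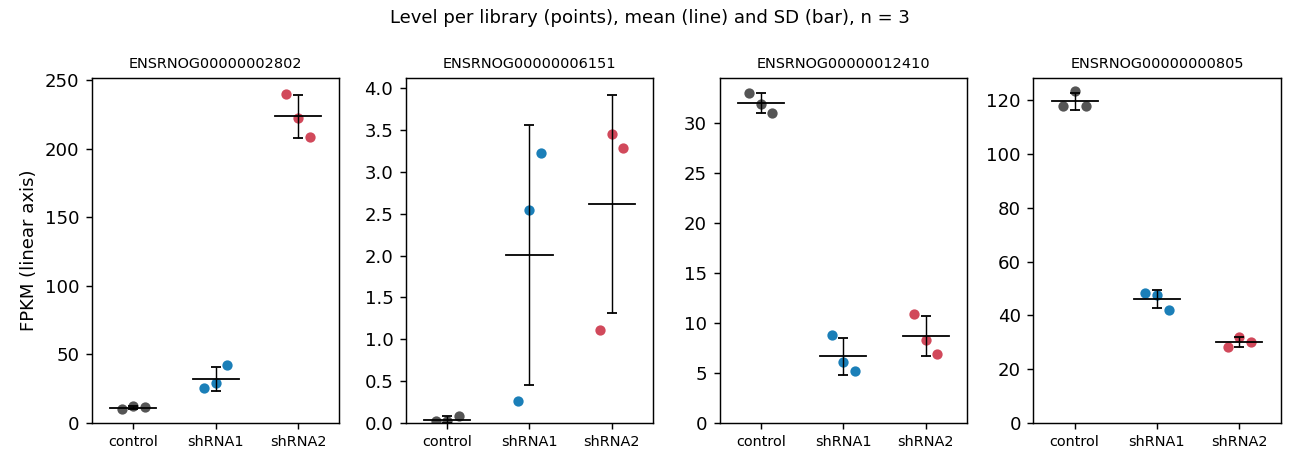
FPKM per library of the 2 genes with the largest shared rise and the 2 with the largest shared fall, with points for libraries, lines for means and bars for SD (n = 3 per group), each panel on its own linear axis from 0. In ENSRNOG00000006151 replicate 1 of shRNA1, at 0.258 FPKM, lies far below the other 2 shRNA1 libraries. Replicate 1 of shRNA2, at 1.11 FPKM, also lies below the other 2 shRNA2 libraries.

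The mean of both hairpins differed from control in 4833 genes (42.1%), 2290 higher and 2543 lower, with 279 changed 2-fold or more. The balance turned to 2741 higher and 2267 lower with median-of-ratios factors. This count does not require that both hairpins act. When the 6 hairpin libraries were fitted as 1 group against the 3 controls, so that the difference between hairpins entered the spread, 801 genes were called.

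The effects of the hairpins also differed from each other, and the difference itself was tested. Between shRNA2 and shRNA1, 6204 genes (54.1%) were called, 3455 higher and 2749 lower with shRNA2, and 607 differed 2-fold or more. All 510 genes that moved in opposite directions were among them, and so were 782 of the 1537 that moved the same way, 642 of which changed more with shRNA2. Among the 4 genes given by identifier the difference was called for ENSRNOG00000002802 (log2 difference 2.79, adjusted p = 3.76e-07) and ENSRNOG00000000805 (-0.60, adjusted p = 3.61e-05), but not for ENSRNOG00000006151 (0.36, adjusted p = 0.498) or ENSRNOG00000012410 (0.34, adjusted p = 0.123). The last was called with library weights (adjusted p = 0.0399) and without shRNA1 replicate 1 (adjusted p = 0.0140), in a range of 0.00770 to 0.372 over its alternatives. Of the 8 largest rises with shRNA1 whose libraries did not overlap those of control, 8 were also called higher with shRNA2. Of the 8 largest such falls, 3 were also called lower with shRNA2, 2 were called higher and 3 were not called, and the difference between hairpins was called for 7. The transcript with the largest fall under shRNA1 changed by 0.25 with shRNA2 (adjusted p = 0.0102), a difference of 2.44 (adjusted p = 1.70e-09). Of the 8 largest rises with shRNA2, 2 were called higher with shRNA1, 1 lower and 5 not at all, and all 8 differed between hairpins. Those 2 were below 1 FPKM in control, and carry-over of shRNA2 reads into shRNA1 libraries was not ruled out for them. Of its 8 largest falls, 6 were called lower with shRNA1 and 2 not at all, and all 8 differed between hairpins. The share of called genes that were higher with shRNA2 than with shRNA1 was 55.7% and became 40.3% after quantile normalization.

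**Figure D4:**
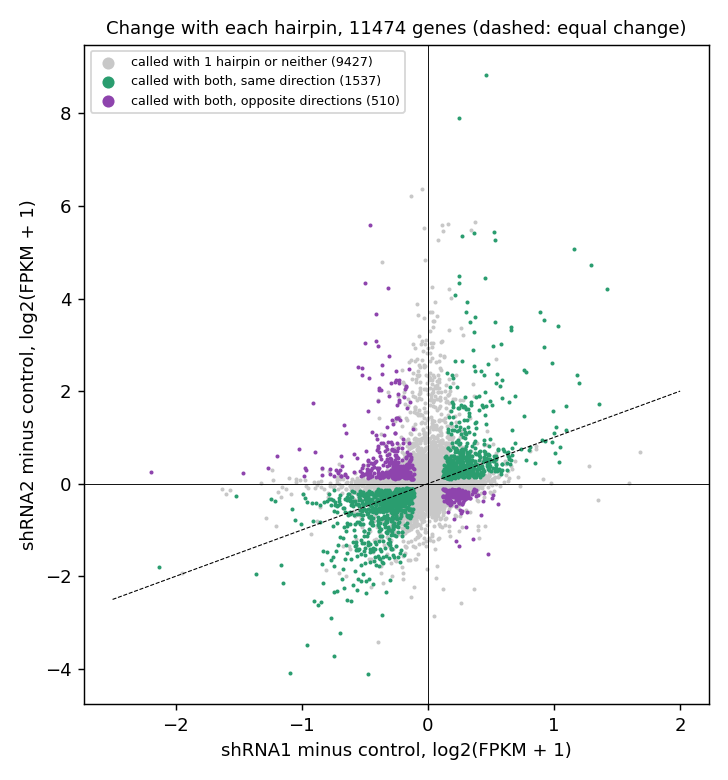
Change against control with shRNA1 (horizontal) and shRNA2 (vertical) on the log2(FPKM + 1) scale, 1 point for each of 11474 genes, with the dashed line at equal change. The 1537 genes called in the same direction and the 510 called in opposite directions are coloured, and the vertical spread far exceeds the horizontal one.

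Over all genes the fold changes of the hairpins correlated weakly. Pearson's r was 0.309 and Spearman's rho 0.327 across 11474 genes, which are not independent replicates, and 60.4% of genes changed with the same sign. Simulated groups without effects gave a median r of 0.502, a rho of 0.462 and 66.7% of genes with the same sign, because both comparisons share the control libraries. The covariance of fold changes was 0.0416, against a simulated median of 0.00524 and a highest simulated value of 0.00749. The difference, 0.0363, estimates the covariance of the effects together with any deviation common to all control libraries, which the simulations do not hold. The 3 control libraries do not divide into sets of 2 libraries for each hairpin, so part of the excess of shared calls over independent lists may come from the shared controls.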

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

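The tests for an exchanged library, for genes chosen by their control level, for the stated Trank1 reductions, for carry-over of reads and for a batch of all replicate 1 libraries were chosen after the values they use had been seen. The other tests below were written down before their outcomes were seen, though the patterns they bear on, and the 2-fold limit, had been chosen from the data.

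The difference between the hairpins was itself tested and was called for 6204 genes, 510 genes were called in opposite directions by the hairpins, and 782 genes were called in the same direction with a different size of change. Among genes given by identifier, ENSRNOG00000002802 differed by 2.79 on the log2 scale (shRNA2 minus shRNA1) and ENSRNOG00000000805 by -0.60.

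More genes changed 2-fold or more with shRNA2 (654) than with shRNA1 (46), at a pseudocount of 1 (914 and 117 at 0.01). A few abundant genes shifting the scale would predict a much lower number after median-of-ratios scaling, which left 657. Lower depth of the shRNA2 libraries would predict little difference among well-measured genes, but of 1506 genes with a mean of at least 20 FPKM, 7.97% changed 2-fold or more with shRNA2 and 1.13% with shRNA1 (6.56% and 1.01% of 1479 genes with at least 20 FPKM in control, a set that rises with shRNA2 cannot enter), and an exchanged single library is argued against by 0 of 9 libraries correlating best with a library of another group, while an exchange of whole groups was not tested. A deeper loss of Trank1 with shRNA2 cannot be told apart from other causes here, since the stated reduction is 35.7% with shRNA2 and 43.4% with shRNA1 but the level was not measured in these libraries. A label of the shRNA2 libraries also gives another hairpin number, so the 35.7% may not belong to their hairpin. A candidate explanation is that shRNA2 acts on transcripts besides Trank1, which stays a hypothesis that was not tested, as does a difference in viral dose.

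Genes moved the same way by both hairpins were more numerous than independent lists give (1537 against 838). Noise of single control libraries as the whole cause is argued against by the covariance of fold changes. It was 0.0375 when each hairpin was set against different controls, above the highest simulated value of 0.00749. A deviation common to all control libraries would stay in both changes and is absent from the simulations, so this test cannot decide on it. For the genes raised by both, carry-over of shRNA2 reads into shRNA1 libraries would need 1 share for all genes, but these 591 genes would need a median of 16.0% of their shRNA2 level, while the 12 genes below 1 FPKM in control and at least 20 FPKM with shRNA2 showed a median of 0.661%. The small rises of such near-silent genes with shRNA1 could still come from carry-over. A response to lower Trank1 and a response to active hairpins in general both stay open as hypotheses. So does a deviation common to all control libraries, and the design holds no test between these.

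Replicate 1 of each hairpin group stood apart from the other replicates, and the deviations of these 2 libraries from their group means correlated at 0.316. A batch of all libraries numbered 1 is argued against by the deviations of control replicate 1, whose correlations with the 2 hairpin libraries were 0.0136 and -0.0690. The response of shRNA1 replicate 1 appeared weaker. Its change had a slope of 0.620 on that of the other 2 replicates, against 0.925 and 1.06 for those replicates. A weaker response would place it between control and the other shRNA1 replicates. It lay so on component 2, at 7.21 against 13.7 and 16.2 for those replicates. On component 3 it scored 8.75, with control at -2.99 to 0.23 and those replicates at -2.06 and -2.05. A weaker response leaves that place unexplained. For shRNA2 replicate 1 the slope was 0.946, close to 1.00 and 0.975 for the others, which argues against a weaker response there. A handling difference common to these 2 libraries stays open.

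Other splits of the samples were tested with fits of the libraries concerned. With 6 libraries there are 10 splits, too few for a share under 0.05, and the real split was the 1 split with the most genes in each case: 3146 for shRNA1 against control with 0 in the highest other split, 5901 for shRNA2 against control with 1, and 5657 for shRNA2 against shRNA1 with 0. For genes moved the same way by both hairpins, 100 splits into 3 groups of 3 were tried. Only the real one gave as many as 1537, and the highest other gave 431. These 100 were a sample of the possible splits, and splits that mix groups move the differences between groups into the spread. The result shows that the libraries form groups, and it cannot decide whether the hairpins agree. For both hairpins against control, 3 of 84 splits into 6 and 3 gave at least the 801 genes of the real split. The other 2 set shRNA1 apart (1270 genes) or shRNA2 apart (4972, the highest), and the highest split that mixed groups called 1 gene. This points to the structure of the samples. Any 3 distinct groups of libraries could give such a share, so it does not bear on an effect common to both hairpins. With 3 groups of 3, as in the report, the real split gave 4833 genes. The highest of the others among the same 100 splits gave 2563, with the same limit.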

How the results depend on the processing

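Leaving out both hairpin libraries numbered 1 and setting each hairpin against different controls were chosen after the data were seen, and so were the counts of genes changed 2-fold or more. For shRNA1, shRNA2, both and shRNA2 against shRNA1 in turn, a mean of at least 5 FPKM left 2138, 3285, 2792 and 3489 genes called, 1021 moved the same way and 382 changed 2-fold with shRNA2, because fewer genes were tested. Requiring a 1.5-fold change left 251, 1326, 727, 1286 and, the same way, 97. With library weights, which lower the weight of variable libraries, 5235 genes were called for shRNA1 and 2591 moved the same way, and the cause was not tested. A fit of 6 against 3 libraries called 801 genes for both hairpins, because the difference between hairpins entered the spread. Genes changed 2-fold with shRNA1 numbered 102 and 117 with pseudocounts of 0.1 and 0.01 and 95 with TPM scaling, where the pseudocount weighs less, and r between hairpins became 0.332, 0.355 and 0.326. Without both hairpin libraries numbered 1, 2378 genes moved the same way and r was 0.335, and with different controls r was 0.264. The cause of these 3 changes was not tested.

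Leaving out each library in turn gave 2167 to 3921 genes for shRNA1, 4975 to 6166 for shRNA2, 3727 to 5304 for both, 5574 to 6168 between hairpins, 1020 to 1912 moved the same way, 34 to 57 and 646 to 674 changed 2-fold with shRNA1 and shRNA2, and r from 0.275 to 0.319. Among the lowest values, 2167 was without shRNA1 replicate 3 and 1020 without control replicate 2. Leaving out shRNA1 replicate 1 gave each of the highest values except 674, which was without shRNA2 replicate 1. The log2 difference of ENSRNOG00000006151, not called between hairpins, went from -0.18 to 0.71 when single libraries were left out. Of 261 alternative values of the 4 genes given by identifier, 248 kept direction and side of the threshold, 8 lost the call (all ENSRNOG00000006151 with shRNA1), 4 gained one (all ENSRNOG00000012410 between hairpins), with the block at adjusted p = 0.0216 in a range of 0.00770 to 0.372 and 1 changed sign.

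With the replicate number as a block, 3253, 5740, 4725 and 6171 genes were called and 1528 moved the same way. Across the 3 groups the numbers do not pair the samples. Same-number deviations correlated from -0.157 to 0.316, over 0.1 in 2 of 9 pairs, and 4 of 9 libraries correlated best with their own number. Both pairs over 0.1 were between the hairpins, where same-number pairs correlated at 0.316, 0.0956 and 0.173. Different-number pairs of hairpin replicates 2 and 3 correlated at 0.129 and 0.142. Whether the numbers pair the hairpin libraries alone was not settled. Tests of gene lists and count-based tests were not run. For the low genes whose values came out whole, the steps gave a median of 17.95 reads per FPKM at the depth of control replicate 1, a counting CV of 23.6% at 1 FPKM and 5.28% at 20 FPKM. This varies with gene length and was not estimated for other genes.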

Other observations

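Of the 38 genes lowered 4-fold or more with shRNA2, 28 were called lower with shRNA1, 0 higher and 10 not at all, with a median log2 change of -0.54 against -2.33 with shRNA2. Of the 183 genes raised 4-fold or more with shRNA2, 49 were called higher with shRNA1, 27 lower and 107 not at all, with a median log2 change of 0.04 against 2.65. Of the 26 genes raised from below 1 FPKM in control to 10 FPKM or more with shRNA2, 9 were called higher with shRNA1 and 17 not at all. Carry-over of shRNA2 reads into shRNA1 libraries was not ruled out for such near-silent genes. The same control libraries enter both changes, and the genes were chosen by their change with shRNA2. The raised and lowered sets were not tested against each other, and they differ in level, with a median of 1.69 FPKM in control for the 183 raised genes and 26.1 FPKM for the 38 lowered ones, while log2(FPKM + 1) shrinks the changes of low genes.

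Of the 31 genes lowered 2-fold or more with shRNA1, 11 were called lower with shRNA2, 5 higher and 15 not at all, and the difference between the hairpins was called for 28. Of the 15 genes raised 2-fold or more with shRNA1, 14 were called higher with shRNA2.

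The share of summed FPKM in the 20 most abundant control transcripts was 16.6% to 17.2% in control libraries, 16.1% to 17.4% with shRNA1 and 12.3% to 13.8% with shRNA2. Listed at 0 in all 3 control libraries and above 0 in all 3 shRNA2 libraries were 73 genes, 2 of them with a mean of at least 1 FPKM. In the other direction, 90 genes were listed at 0 in all 3 shRNA2 libraries and above 0 in all 3 control libraries, 0 of them with such a mean. Listing at 0 depends on depth, and the estimated mean relative depth was 0.981 for shRNA2 and 1.16 for control. For shRNA1 against control there were 48 genes in each direction.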
